A study of Homo sapiens with 6 samples.

How the data were processed

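RNA was measured by sequencing in 6 cultures of the colorectal carcinoma cell line HCT116, 3 labelled wild type and 3 labelled Rab27B KO, all untreated and grown for 48 hours. Per the labels' protocols, RNA was isolated with a column kit and libraries were made on the DNBSEQ platform by a sequencing service. HISAT and Bowtie2 and the genome build GRCh38 are named in the submitters' processing notes. Their roles, the counting, the annotation, the scaling between samples and the statistical test are not given in the sources used here. The submitters state that the 3 samples of each genotype are biological replicates. All 6 samples were grouped by their titles, which match the genotype labels in each sample.

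The data analysed here were 2 tables without values per sample. Per the file headers, they give a log2 fold change of Rab27B KO over wild type for each gene and a q-value from the authors' test. The table of higher genes also holds the deposited linear ratio of the same fold, which equalled 2 to the power of the log2 value within a relative difference of 4.53e-10. All values in 1 table are above 0 and all in the other below 0, and every q-value is below 0.05, so the tables hold only genes that passed that threshold. Genes that did not pass, or were not measured, are not analysed here, and how many genes were tested is unknown. For 17 genes the q-value is listed as 0. The number of counts behind a gene is unknown, so no interval on a fold change and no detection floor can be given, and folds of genes with few reads cannot be told from those of abundant genes except by their q-values. Because q-values depend on abundance and transcript length, long and abundant transcripts are more easily listed. No column of per-sample values was present in the 2 tables.

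The design fixed before the data were examined foresaw a test on counts or on normalized values if samples were given, and otherwise the authors' q-values at 0.05 with no test added. The last case applied. List-wise readjustment of q-values (adjusted over the list alone) could not be made, since unadjusted p-values were not analysed here. Gene IDs were matched to a RefSeq gene table of GRCh38.p14: 7656 of 7681 matched and 25 did not. Coordinates are from that table and are 1-based. For 1 gene ID, 10533, the table prints the symbol PITRM1, which also stands at ID 10531. The reference gives ATG7 for 10533, and that gene was counted as ATG7, with a log2 fold change of 0.21 and q = 0.0455 in the authors' deposited table.

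The 23 gene lists were written before the data were examined, from general knowledge of pathways and cell type markers. They hold 644 distinct listed genes, 25 of them in more than 1 list. Since the tables give no unchanged genes, a list was tested only for its direction: the number of listed members higher and lower was compared with the other listed genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists with at least 5 listed members. The same test was run per chromosome over 23 chromosomes. A logistic model of direction, chosen after seeing the data, added log2 transcript length with its square, GC content and chromosome, with a likelihood ratio test for list membership. Lengths and GC content came from the longest protein-coding transcript of each gene in GENCODE release 29 and were found for 7610 genes. Intervals on shares are 95% Wilson intervals over genes and cover counting error only.

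The genes named were RAB27B and RAB27A, the 10 largest log2 rises and the 10 largest falls, and up to 4 listed members per list with the smallest q-value. The rule also asked for a minimum level and for separation of the samples, which could not be applied without values per sample. Names starting with LOC or LINC were left out. A few genes that the rule would name are not reported here. Genes outside the rule are said to have been chosen after their values were seen. Where values in a list were tied at a q-value of 0, the larger change came first.

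Fisher's test and a logistic model without chromosome were run on simulated data before use. With 7681 genes, lists of 28 listed genes with 80% higher were called in 90 of 100 simulations and lists of 53 in 100 of 100. Lists with no effect were called in 3 of 100 at either size. When direction followed transcript length alone, lists of short genes were called by Fisher's test in 71 and 95 of 100 simulations at 28 and 53 genes. The logistic model with length and GC content but without chromosome called them in 5 and 6. The form with chromosome, which was used for the lists, was not simulated. Simulated directions were drawn independently for each gene, and a call there meant an unadjusted p below 0.05. Rates of false calls for co-regulated genes, whose directions go together, were therefore not measured. Alternatives tried were a q-value below 0.01, a log2 change of at least 1, gene symbols as printed, leaving out 4 chromosomes, and the logistic model. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.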

Results

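HCT116 is a human colorectal carcinoma cell line. The study profiled its transcriptome by RNA sequencing in 6 untreated cultures, 3 of wild-type cells and 3 labelled as carrying a CRISPR/Cas9 deletion of RAB27B, a small GTPase of secretory vesicles and lysosome-related organelles. The question was how loss of RAB27B affects these cells, with regulation of autophagy named in the study title. The deposited data analysed here were 2 tables of the authors' own comparison, 1 for genes higher and 1 for genes lower in the samples labelled Rab27B KO, each gene with a log2 fold change and a q-value. No value per sample was analysed here, so the depth of each sample and the spread between its replicates are unknown, and no standard error can be given for a fold change. The tables held 7681 genes, of which 7656 were typed as mRNA, 16 as lncRNA and 9 as pseudogenes. Every listed gene had a q-value below 0.05, the largest being 0.0499963.

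The transcript of the targeted gene went against the label. RAB27B (gene ID 5874; GRCh38 chromosome 18, 54717857 to 54895516) was 36.7-fold higher in the samples labelled Rab27B KO in the authors' deposited table, a log2 fold change of 5.20 with a q-value listed as 0. Its paralog RAB27A was in neither table. Each direction given from here on is therefore that of the samples labelled Rab27B KO relative to those labelled wild type, as the column headers state it. An edited gene can still give RNA, and an RNA level does not measure the protein. Of the listed genes starting within 1 Mb of RAB27B, CCDC68 was 3.42-fold and MBD2 1.34-fold higher and POLI 1.81-fold lower in the authors' deposited table. Only CCDC68 lies within 100 kb. These neighbours were chosen after their values were seen.

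The changes were many and mostly small. The authors' deposited table listed 3898 genes as higher and 3783 as lower, so that 50.7% of the listed genes were higher. The median higher gene had a log2 fold change of 0.41 and the median lower gene one of -0.41. A log2 change of 1 or more was listed for 469 higher and 499 lower genes, and one of 2 or more for 145 higher and 191 lower genes.

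The largest rises included interferons, a chemokine and keratins. In the authors' deposited table the interferon genes IFNL2, IFNL1 and IFNB1 had log2 fold changes of 6.22 (q = 2.58e-15), 5.75 (q = 2.25e-21) and 5.46 (q = 5.67e-04). Those of the keratins KRT16 and KRT14, typical of squamous epithelium, were 6.12 and 5.94 in the authors' deposited table. CXCL10, an interferon-induced chemokine, stood at 6.04 in the authors' deposited table. Also among the 10 largest rises in the authors' deposited table were PGBD3 at 5.71 (q = 3.33e-04), ROBO4 at 5.61 (q = 4.13e-04) and CALB1 at 5.36 (q = 8.65e-04). Few reads may lie behind large folds with q-values of this size, as for IFNB1 too. IFNL2 and the keratins have near-identical paralogs or pseudogenes, and PGBD3 lies within another gene, so their values are uncertain where reads were shared.

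The largest falls were in genes of several kinds. MUC13, a transmembrane mucin of the intestine, had a log2 fold change of -6.46 (q = 2.50e-06) in the authors' deposited table, and MGAM, the brush-border maltase-glucoamylase, one of -6.39. The lowest values in the authors' deposited table belonged to RBBP8NL at -9.44 and MAGEB1, a cancer-testis antigen, at -9.39. FLRT3 followed at -8.07, NOSTRIN at -7.33, EXO5 at -6.99, SMIM22 at -6.40 and ZNF615 at -6.12 in the authors' deposited table. Whether a genotype had almost no reads of these genes is unknown, and how such genes were handled is not given in the sources used here.

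Autophagy and lysosome genes were higher far more often than lower. Of 49 genes of the autophagy machinery 29 were listed, 23 higher and 6 lower. Among them MAP1LC3B, which encodes the autophagosome marker LC3B, was 1.65-fold higher (q = 1.25e-45) in the authors' deposited table. ATG12, WIPI1 and WDR45B were 1.70-fold, 1.86-fold and 1.27-fold higher in the authors' deposited table. The 6 lower members included the initiation kinase ULK1 at a log2 fold change of -0.34 and its partner RB1CC1 at -0.48 in the authors' deposited table, both chosen after their values were seen. Of 28 autophagy receptors and stress-induced autophagy genes 19 were listed, 16 higher and 3 lower. The cargo receptor SQSTM1 (p62) was 1.78-fold higher (q = 6.09e-101) in the authors' deposited table. BNIP3, CALCOCO2 and DDIT4 were 2.18-fold, 1.80-fold and 1.77-fold higher in the authors' deposited table. The lysosome and CLEAR network list, which holds lysosomal enzymes, the proton pump and their regulators, had 54 of 81 genes listed, 49 higher and 5 lower. The protease gene CTSD was 1.56-fold and CTSA 1.53-fold higher, whereas the cholesterol carrier NPC2 was 1.97-fold and the protease gene CTSH 2.75-fold lower in the authors' deposited table. TFEB, the transcription factor of this network, was 1.40-fold higher in the authors' deposited table and was chosen after its value was seen. Fisher's exact test (two-sided, Benjamini-Hochberg over 23 lists) set each split against the other listed genes. It gave an adjusted p of 0.0054 for the machinery, 0.00854 for the receptors and 9.66e-09 for the lysosome list. Most of these changes were small. No listed machinery gene reached a log2 change of 1, the largest being WIPI1 at 0.89 in the authors' deposited table. At a log2 change of at least 1 each of these lists had fewer than 5 members and could not be tested.

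**Figure D1:**
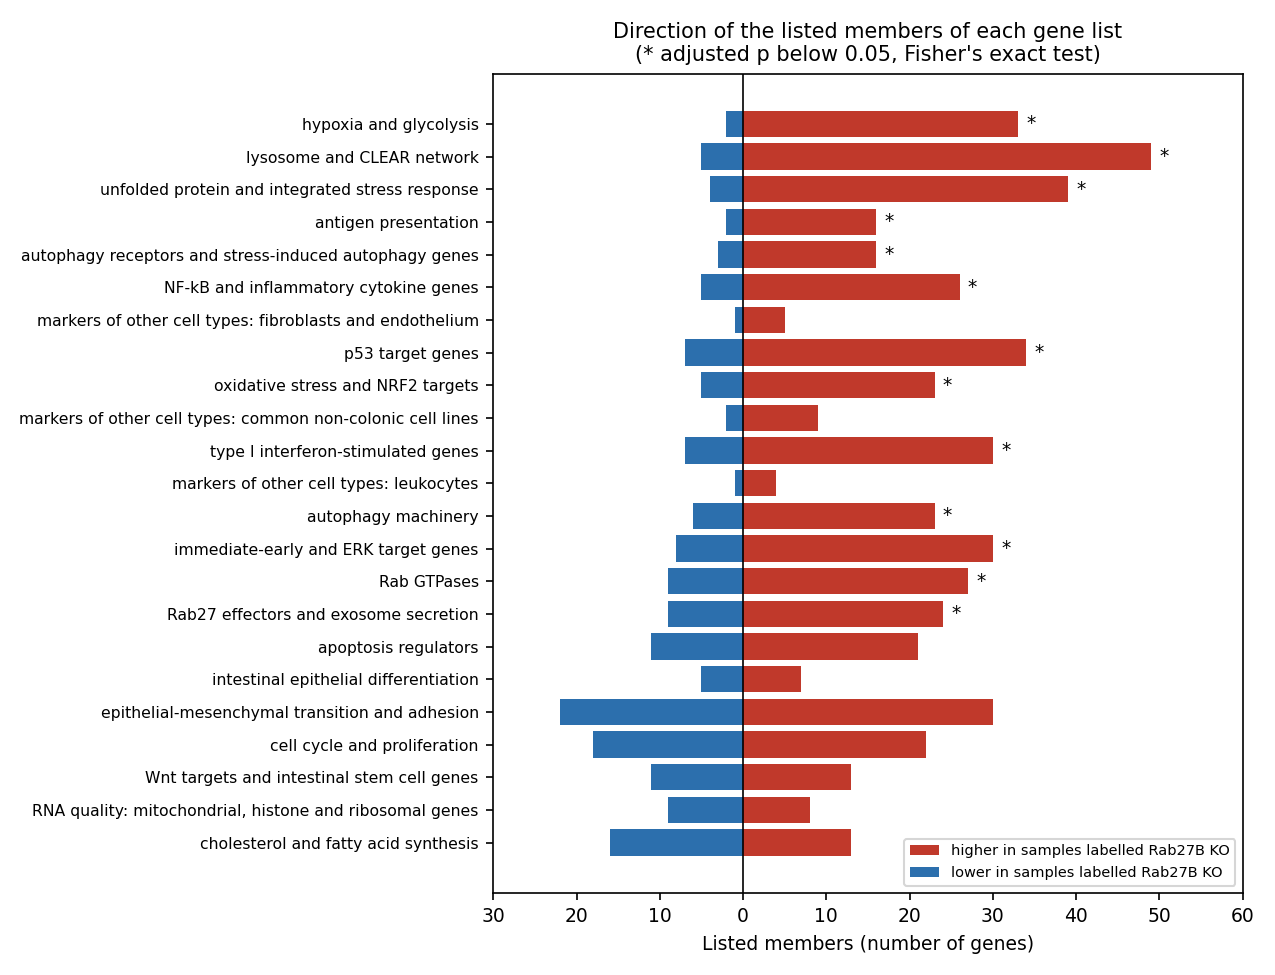
Number of listed members of each of 23 gene lists that were higher (red, right) or lower (blue, left) in the samples labelled Rab27B KO; the horizontal axis counts genes and an asterisk marks an adjusted p below 0.05 by Fisher's exact test. The 13 marked lists all lean to the right, from 24 higher and 9 lower for Rab27 effectors and exosome secretion to 33 higher and 2 lower for hypoxia and glycolysis.

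Genes of vesicle traffic leaned the same way. Of 60 Rab GTPases other than RAB27B, 36 were listed, 27 higher and 9 lower (adjusted p = 0.00835, Fisher's exact test). RAB3A, RAB13 and RAB5C were 2.07-fold, 1.45-fold and 1.32-fold higher and RAB25, an epithelial Rab, 1.70-fold lower in the authors' deposited table. The largest changes of the list were falls, in RAB9B (log2 fold change -4.20, q = 8.78e-03) and RAB19 (-1.09) in the authors' deposited table. Both were chosen after their values were seen. The median of the Rab list was 0.27 and its mean 0.06. Of 52 Rab27 effectors and exosome genes 33 were listed, 24 higher and 9 lower (adjusted p = 0.0242, Fisher's exact test). The tetraspanin CD9 was 1.61-fold and FLOT1 1.48-fold higher in the authors' deposited table. The Rab27 effectors UNC13D (Munc13-4) and MLPH were 5.18-fold and 1.42-fold lower in the authors' deposited table. Other listed effectors went both ways. Log2 fold changes in the authors' deposited table were -0.89 for EXPH5 and -0.44 for SYTL1, against 0.56 for SYTL2 and 0.57 for SYTL5. These other effectors were chosen after their values were seen. The lean of this list therefore cannot be read as a rise of the effectors. This list lost its call at a q-value below 0.01, where 16 genes were higher and 9 lower (adjusted p = 0.355, Fisher's exact test). It also lost it without chromosomes 4, 7, 13 and 15, where 22 were higher and 7 lower (adjusted p = 0.0617, Fisher's exact test), within a range of 0.0181 to 0.355 over its 4 alternatives.

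Interferon, inflammatory and antigen presentation genes were mostly higher. Of 57 type I interferon-stimulated genes 37 were listed, 30 higher and 7 lower (adjusted p = 0.000751, Fisher's exact test). The antiviral genes OASL, IFIT2, IFIT1 and ISG15 were 19.9-fold, 12.1-fold, 9.18-fold and 4.31-fold higher in the authors' deposited table. Of 47 NF-kB and inflammatory cytokine genes 31 were listed, 26 higher and 5 lower (adjusted p = 0.000751, Fisher's exact test). NFKB2 and NFKBIA were 1.82-fold and 1.88-fold higher, but the adhesion receptor gene ICAM1 and the cytokine gene IL32 were 46.4-fold and 64.6-fold lower in the authors' deposited table. The chemokine gene CXCL8, chosen after its value was seen, was 16.3-fold higher in the authors' deposited table. Of 31 antigen presentation genes 18 were listed, 16 higher and 2 lower (adjusted p = 0.00338, Fisher's exact test). HLA-B and HLA-C were 1.67-fold and 1.59-fold higher and the chaperone gene CALR 1.56-fold higher in the authors' deposited table. HLA genes are polymorphic paralogs, and their reads can be shared.

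**Figure D2:**
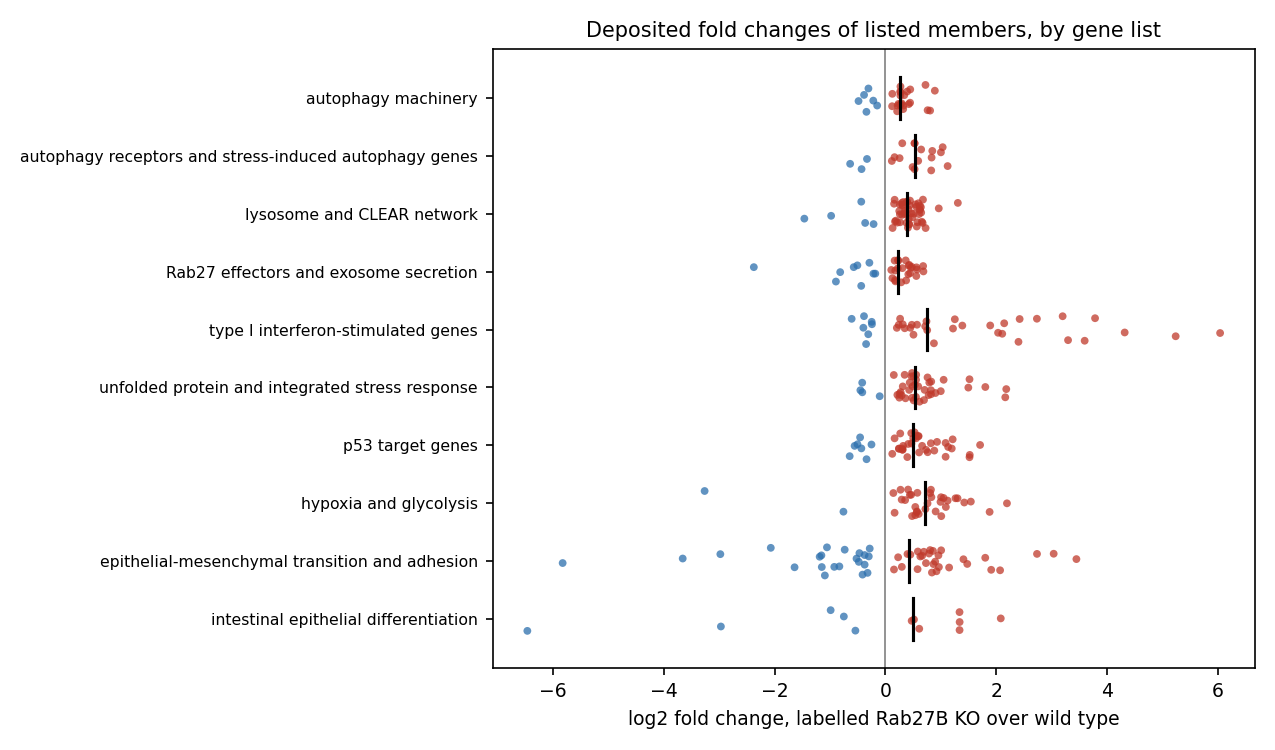
Deposited log2 fold change of each listed member of 10 gene lists; each point is a gene, red if higher and blue if lower in the samples labelled Rab27B KO, vertical scatter within a list has no meaning, and the black bar is the median. The interferon-stimulated genes reach 6.04 (CXCL10), while the lysosome genes lie close together around a median of 0.40.

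Stress response genes were mostly higher as well. For the unfolded protein and integrated stress response 43 of 52 genes were listed, 39 higher and 4 lower (adjusted p = 2.93e-07, Fisher's exact test). ATF3 was 4.48-fold, GDF15 2.86-fold, HERPUD1 2.00-fold and HSPA5, the ER chaperone BiP, 1.77-fold higher in the authors' deposited table. For hypoxia and glycolysis 35 of 46 genes were listed, 33 higher and 2 lower (adjusted p = 2.93e-07, Fisher's exact test). NDRG1, ENO2, P4HA1 and PGK1 were 3.68-fold, 2.91-fold, 2.68-fold and 1.78-fold higher in the authors' deposited table. CA9, a hypoxia-induced carbonic anhydrase chosen after its value was seen, was 9.59-fold lower in the authors' deposited table. For p53 targets 41 of 53 genes were listed, 34 higher and 7 lower (adjusted p = 0.00015, Fisher's exact test). CDKN1A (p21) was 3.27-fold, SFN 2.32-fold and PLK2 2.12-fold higher in the authors' deposited table. For oxidative stress and NRF2 targets 28 of 47 genes were listed, 23 higher and 5 lower (adjusted p = 0.00266, Fisher's exact test). Its members with the smallest q-values in the authors' deposited table were the metallothionein genes MT1X, MT2A and MT1E, which bind metal ions, at 4.07-fold, 2.54-fold and 1.96-fold higher, and the ferritin gene FTH1 at 1.76-fold higher. For immediate-early and ERK target genes 38 of 46 were listed, 30 higher and 8 lower (adjusted p = 0.00158, Fisher's exact test). KLF4, JUN, DUSP4 and FOSL1 were 4.51-fold, 3.76-fold, 2.03-fold and 1.99-fold higher in the authors' deposited table. The 8 lower members included ETV4, MYC and EGR1, at log2 fold changes of -0.75, -0.53 and -0.27 in the authors' deposited table. These lower genes were chosen after their values were seen.

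Lists of proliferation, stemness, adhesion, differentiation, lipid synthesis and apoptosis held members that changed in both directions. Of 66 cell cycle genes 40 were listed, 22 higher and 18 lower (adjusted p = 0.732, Fisher's exact test). CCND1 was 1.60-fold and CDC25B 1.53-fold higher in the authors' deposited table, and MKI67 and MCM5, chosen after their values were seen, were each 1.31-fold lower. Of 48 Wnt target and stem cell genes 24 were listed, 13 higher and 11 lower (adjusted p = 0.839, Fisher's exact test). The Wnt antagonist gene DKK1 was 13.3-fold higher, and SOX4 and RNF43 were 4.47-fold and 3.03-fold lower in the authors' deposited table. Of 72 epithelial-mesenchymal transition and adhesion genes 52 were listed, 30 higher and 22 lower (adjusted p = 0.45, Fisher's exact test). Since this list holds both epithelial and mesenchymal genes, its split cannot show whether 1 kind rose while the other fell. VIM (vimentin) was 8.21-fold, PLAUR 4.20-fold and ITGB4 3.49-fold higher and EPCAM 2.23-fold lower in the authors' deposited table. ZEB1, a repressor of epithelial genes, was 6.66-fold higher and CDH1 (E-cadherin) 2.22-fold lower in the authors' deposited table, both chosen after their values were seen. Of 54 intestinal differentiation genes only 12 were listed, 7 higher and 5 lower (adjusted p = 0.839, Fisher's exact test). HNF4A, a gut transcription factor, was 7.82-fold lower, and CA2, KRT8 and KRT18 were 2.53-fold, 1.53-fold and 1.39-fold higher in the authors' deposited table. KRT20, chosen after its value was seen, was 4.23-fold higher in the authors' deposited table. The median log2 fold change of this list was 0.50 and its mean -0.33. Of 42 cholesterol and fatty acid synthesis genes 29 were listed, 13 higher and 16 lower (adjusted p = 0.701, Fisher's exact test), with a median of -0.13 and a mean of 0.03. ELOVL6, which elongates fatty acids, was 2.23-fold lower and ACSS2 1.89-fold higher in the authors' deposited table. Of 51 apoptosis regulators 32 were listed, 21 higher and 11 lower (adjusted p = 0.17, Fisher's exact test); without chromosomes 4, 7, 13 and 15 this list was called, with an adjusted p of 0.0351 within a range of 0.0351 to 0.302 over its 4 alternatives. BIRC3 and PMAIP1 (NOXA) were 4.06-fold and 2.29-fold higher in the authors' deposited table. Because the list holds genes that promote and genes that restrain cell death, its split gives no direction for apoptosis.

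Some markers of other cell types were listed, most of them higher. Of 26 leukocyte markers 5 were listed, 4 higher and 1 lower (adjusted p = 0.479, Fisher's exact test), with CD68 3.51-fold higher in the authors' deposited table. Of 24 fibroblast and endothelial markers 6 were listed, 5 higher and 1 lower (adjusted p = 0.315, Fisher's exact test), with COL3A1 3.41-fold higher in the authors' deposited table. Of 26 markers of common non-colonic cell lines 11 were listed, 9 higher and 2 lower (adjusted p = 0.108, Fisher's exact test). Among genes with a log2 change of at least 1 this list was called, with an adjusted p of 0.0363 within a range of 0.0363 to 0.355 over its 5 alternatives. KRT17 and KRT5, keratins of basal epithelium, had log2 fold changes of 3.59 and 2.27 in the authors' deposited table. The lung marker SFTPC, chosen after its value was seen, was 18.8-fold higher in the authors' deposited table, with a q-value of only 0.0111. SERPINA1, 1 of the 2 lower members, was 1.59-fold lower in the authors' deposited table. The list of mitochondrial, histone and ribosomal genes had 17 of 39 genes listed, 8 higher and 9 lower (adjusted p = 0.839, Fisher's exact test). Its 8 higher members were histone genes, such as H1-2 at 3.91-fold, and its 9 lower members ribosomal protein genes, such as RPL3 at a log2 fold change of -0.31 in the authors' deposited table. The median of that list was -0.10 and its mean 0.37. None of its 13 mitochondrial genes was listed, and neither was any other gene of the mitochondrial chromosome, so whether the authors' comparison held these genes at all is unknown. Of the 39 genes 1 is a pseudogene, MTCO2P12, taken in through the name MT-CO2 and not listed.

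The direction of change also depended on where a gene lies and how long its transcript is. On chromosomes 13, 4 and 15 only 13.5% (20 of 148), 16.8% (50 of 298) and 19.8% (51 of 257) of the listed genes were higher. On chromosome 7 the share was 33.0% (132 of 400). The 95% Wilson intervals were 8.92 to 19.95% for chromosome 13, 12.96 to 21.4% for chromosome 4, 15.4 to 25.1% for chromosome 15 and 28.6 to 37.8% for chromosome 7. Fisher's exact test against the other listed genes, adjusted over 23 chromosomes, gave 9.69e-21, 6.07e-34, 3.95e-24 and 1.49e-12 for chromosomes 13, 4, 15 and 7. Among the genes with a log2 change of at least 1, chromosomes 4, 7 and 13 still held more lower than higher genes (18 higher and 35 lower, 15 and 33, 1 and 11) but were no longer called, with adjusted p-values of 0.111, 0.099 and 0.0727 by Fisher's exact test. Chromosome 15 was still called there, with 8 higher and 32 lower (adjusted p = 0.0062, Fisher's exact test). Chromosomes 1, 3, 9, 12, 19 and 20 were called in the other direction, with 56.5% (chromosome 12) to 64.3% (chromosome 20) of the listed genes higher and adjusted p-values of at most 0.0431 by Fisher's exact test. With transcript length and GC content in a logistic model chromosome 19 lost this call and the other 5 kept it. Chromosomes 2 and 5 were newly called as higher there and chromosome 11 as lower. Each of these tests set a chromosome against all other listed genes, including those on chromosomes 4, 7, 13 and 15. Without these 4 chromosomes 3645 listed genes were higher and 2933 lower. Calls to higher may therefore in part mirror the low chromosomes, which was not tested. Within chromosome 7 the share was 11.3% (13 of 115) from 0 to 40 Mb and 41.8% (119 of 285) beyond, a cut chosen after its values were seen. On chromosome 11 from 20 to 40 Mb, a region chosen after its values were seen, 1 of 24 listed genes was higher. When the listed genes were divided into 5 equal groups by transcript length, 73.9% were higher in the shortest group, up to 1991 bases, against 30.2% in the longest, from 5958 bases. The 13 lists that leaned to higher kept their calls in a logistic model with transcript length, GC content and chromosome as covariates. Genes are not independent replicates, so these p-values describe the composition of the 2 tables.

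**Figure D3:**
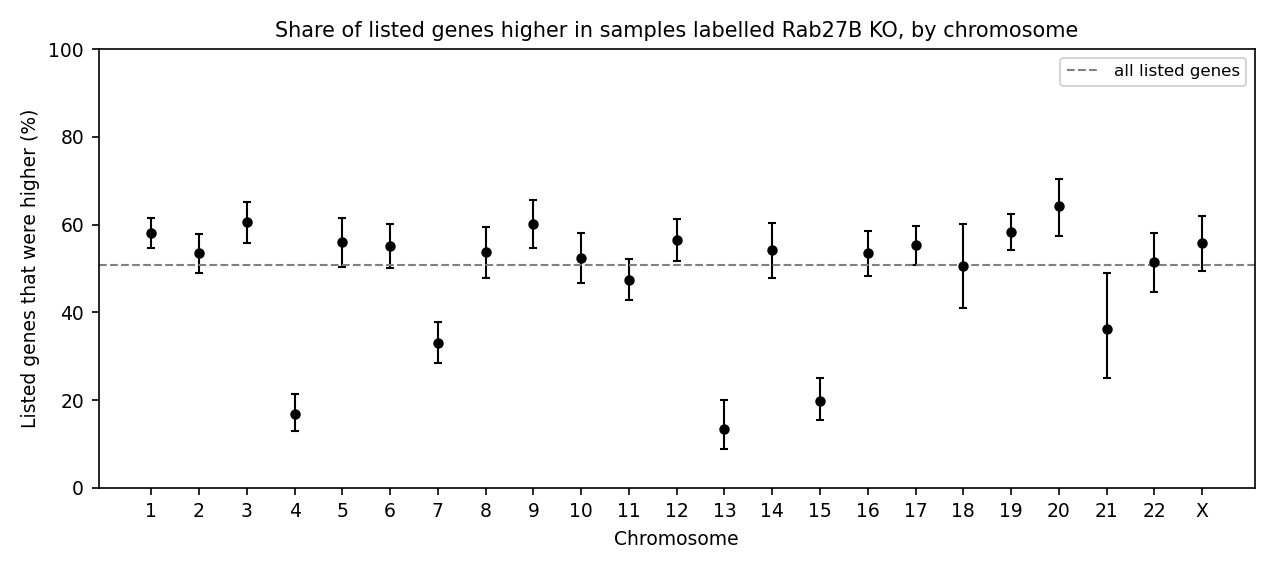
Percent of listed genes on each chromosome that were higher in the samples labelled Rab27B KO, with 95% Wilson intervals; the dashed line is the share over all listed genes, 50.7%. Chromosomes 4, 13 and 15 lie at 16.8%, 13.5% and 19.8%, and chromosome 7 at 33.0%.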

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

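No paired analysis was possible because the tables carry no columns per sample; for the same reason no fit with a replicate block, no leaving out of replicates, no other normalization, count filter, pseudocount or tool, no camera or fry set test and no count of other splits of the samples could be run. Leaving out chromosomes 4, 7, 13 and 15, printed symbols and the logistic model were chosen after seeing the data, and so was testing chromosomes. A log2 change of at least 1 left 469 higher and 499 lower genes. It left 8 lists with an excess of higher members in place of 13. Of the 13, 7 were still called and 6 had fewer than 5 members and gave no value. Those 6 were both autophagy lists, the lysosome list, Rab GTPases, Rab27 effectors and exosome secretion, and antigen presentation. The list added to the 7, markers of common non-colonic cell lines, had an adjusted p of 0.0363 there by Fisher's exact test. At that setting chromosomes 4, 7 and 13 still leaned to lower (18 higher and 35 lower, 15 and 33, 1 and 11) but were no longer called, with adjusted p-values of 0.111, 0.099 and 0.0727 by Fisher's exact test. Chromosome 15 was still called, with 8 higher and 32 lower (adjusted p = 0.0062, Fisher's exact test). The Rab27 effector and exosome list was not called at a q-value below 0.01 (16 higher and 9 lower, adjusted p = 0.355, Fisher's exact test) or without the 4 chromosomes (22 and 7, 0.0617), and apoptosis regulators were called without those chromosomes (0.0351). The cause was not tested. The other 12 called lists kept direction and call under each alternative that gave a value, with adjusted p-values of at most 0.0363. The missing depth limits every statement on single genes.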

Other observations

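All tests in this part were chosen after the values were seen. Several gene families, picked by symbol, leaned to 1 direction in the authors' deposited table. Some of the ribosomal protein, histone and keratin genes among them are also in the fixed lists. Of 219 listed genes with a symbol starting ZNF, most of which encode zinc-finger transcription factors, 205 were lower and 14 higher, with a median log2 fold change of -0.55 (adjusted p over 13 families = 3.52e-46, Fisher's exact test). They were lower both on chromosome 19, where 3 of 84 were higher, and elsewhere, where 11 of 135 were. Nucleoporins were lower in 17 of 18 cases, HOX genes in 14 of 18 and the lysine demethylases and methyltransferases in 13 of 14. Proteasome subunits were higher in 32 of 33 cases, complex I subunits in 23 of 24 and subunits of complexes III, IV and V in 30 of 32. Cytosolic ribosomal proteins went the other way, with 32 of 43 lower and a median of -0.16, although their transcripts are short. Replication-dependent histone genes were higher in 12 of 12 cases, with a median of 1.53. Their median transcript length was only 650.5 bases. The logistic model with transcript length, GC content and chromosome gave no value for them, so length was not accounted for there. Annexins were higher in 9 of 10 cases. Mitochondrial ribosomal proteins were higher in 26 of 38 cases and S100 proteins in 10 of 11 (adjusted p = 0.0339 and 0.0153, Fisher's exact test), but neither was called with transcript length, GC content and chromosome in a logistic model (0.801 and 0.824).

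Keratins were higher in 18 of 19 cases, with a median log2 fold change of 2.08. KRT6B and KRT6A were 26.4-fold (q = 2.25e-03) and 24.0-fold (q = 3.81e-03) higher in the authors' deposited table, beside KRT14 and KRT16. SNAI2, a transcription factor of basal and mesenchymal cells, was 3.76-fold higher, and CDX2, the intestinal homeobox gene, was 1.68-fold lower in the authors' deposited table. TGFBI was 56.6-fold lower in the authors' deposited table. The interferon genes included IFNL3 at 20.4-fold higher in the authors' deposited table, a near-identical paralog of IFNL2.

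RAB27B was listed with a log2 fold change of 5.20 in the samples labelled Rab27B KO. A gain of the whole chromosome 18 segment within 1 Mb is argued against by the neighbours. The listed genes starting there, MBD2, POLI and CCDC68, had log2 fold changes of 0.42, -0.86 and 1.77 in the authors' deposited table, with a median of 0.42. A gain of a smaller segment stays open, since CCDC68 at 1.77 is the only listed gene within 100 kb and cannot decide it. An inverted ratio, or group labels exchanged between the groups, could give the value and cannot be told apart from a true rise of the edited transcript: no second gene marks the genotype, and 5.20 is the only value that bears on it. If the ratio were inverted, every direction reported above would turn, including those of the autophagy and lysosome lists.

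The excess of lower genes on chromosomes 4, 7, 13 and 15 is not explained by transcript length and GC content, since with both in the model the largest adjusted p of the 4 was 2.14e-13. On chromosome 7, 7 of the 8 bins of 20 Mb with 10 or more listed genes had more lower than higher genes. The highest share of higher genes in a bin there was 50%. On chromosomes 4, 13 and 15 all 19 such bins had more lower than higher genes. A lower dosage of whole chromosomes would give this direction, but the size of the shift was not tested. The median log2 fold change of the listed genes was -0.43, -0.43 and -0.41 on chromosomes 4, 13 and 15. The median lower gene of all chromosomes stood at -0.41. A candidate explanation is that the labelled knockout cells carry fewer copies of chromosomes 4, 13 and 15 relative to the rest than the wild-type cells do. If the ratio were inverted, which the RAB27B value of 5.20 leaves open, the lower dosage would instead lie in the cells labelled wild type. This is a hypothesis found and tested on the same genes; no DNA was measured, and whether it would reflect a clonal derivative of HCT116, another line or the deletion itself was not tested.

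The direction of change followed transcript length, with a Spearman rho of -0.28 across 7610 genes, which are not independent replicates. Length, GC content and chromosome, as modelled, do not account for the whole lean of the gene lists: 0 of the 13 lists lost the call with these in the model. Nor do they account for the whole lean of the zinc-finger genes, whose adjusted p was 5.47e-40 in that model (likelihood ratio test). The length used was that of the longest annotated transcript, which need not be the one expressed, so a remaining effect of length is not excluded. A difference in RNA integrity or library preparation between the groups may still underlie the trend itself and cannot be told apart from a biological difference, because no value per sample is there to set the rho of -0.28 against.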
